A study of Mus musculus with 19 samples.

How the data were processed

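The series holds 19 samples of mouse hippocampal neurons from embryonic day 17, cultured for 10 days. They comprise 9 RNA-seq libraries (3 treatments with 3 libraries each), 3 bisulfite libraries (1 per treatment), 4 H3K27ac and 2 H3K4me1 ChIP-seq samples, and 1 input sample, which is not used here. Groups were taken from the sample labels. Bic/4AP lasted 3 h, and the time of TTX is not given in the sources used here. RNA and ChIP samples came from ICR mice and bisulfite libraries from C57BL/6 mice, so methylation values do not come from the same animals as the other values.

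Per the labels' protocols, RNA was selected by poly(A) and made into libraries with the NEBNext Ultra Directional kit. The deposited expression values are RPKM, in which read numbers are divided by gene length and library size, with 1 value per gene and library. Whether counting used the strand, and whether duplicate reads were removed, is not given in the sources used here, so antisense and overlapping genes cannot be told apart. TopHat, Bowtie2 2.2.4, SAMtools 0.1.19, MACS 1.4.1 and the mm10 build are named per the submitters' processing notes, TopHat for the first deposits alone. Per the labels, bisulfite libraries used the EZ DNA Methylation-Gold kit and post-bisulfite adaptor tagging, in which adaptors are added after conversion. The deposited methylation values are a fraction from 0 to 1 for each CpG, without coverage, so the depth is unknown and no counting interval is given. The peak lists name each peak as a MACS peak and give the authors' score per peak, 50 or higher in every list. The lists are per sample, and use of the input in calling is not given in the sources used here.

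The RPKM values of a gene are whole multiples of what 1 read is worth. This was checked for 19592 genes above 0 in 3 or more libraries, and the values of 19589 of them came out whole within 0.15 of a read. The recovered library sizes are 12.6, 11.9 and 9.68 M reads with TTX, 5.63, 9.97 and 5.74 M untreated and 4.52, 4.59 and 4.34 M with Bic/4AP. One read of a gene of 1 kb was worth between 0.0791 and 0.230 RPKM. The median SD of log2 values inside a group was 0.143 untreated, 0.0716 with TTX and 0.102 with Bic/4AP. The expression files hold 24062 lines, of which 27 carry a name turned into a date and 4 with a repeated name were left out. Of 24058 names, 22550 matched a RefSeq symbol and 1335 a synonym in a table of the GRCm38 assembly. None of the 13 mitochondrial transcripts meant as a check of RNA quality is among the gene names of the files, so that check was not made.

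Tests were planned for read counts, with a fallback for normalized values. Because the values are RPKM, the fallback was used: limma 3.58.1 in R 4.3.3 with an intensity trend on log2(RPKM + 1), for genes at 1 RPKM or more in at least 3 libraries. All 9 libraries entered 1 fit with treatment as the term, and genes passed at a Benjamini-Hochberg adjusted p of 0.05. The scale understates changes of low genes. The 14801 genes tested include 400 microRNA and small nucleolar RNA genes. The 16 gene lists with measured members cover rapid and late activity genes, MAP kinase feedback, excitatory and inhibitory synapse, interneuron peptides, DNA methylation, histone acetylation, voltage-gated channels, stress and death, and markers of astrocytes, oligodendrocyte lineage, microglia, vascular and mural cells, progenitors and neurons. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether members move on balance one way and compares no list with other genes. In Bic/4AP against untreated and against TTX every camera call was lost with the estimated correlation. In TTX against untreated the calls of the choroid plexus list and of the list of RNAs without poly(A) tails held. List p-values were adjusted over the 16 lists and, separately, over the 3 lists added after the data were seen. Both calls that held belong to those 3 lists. Choices of the tests of the comparisons, lists, named genes and alternatives were made before the data were examined, except for quantile and cyclic loess normalization, links at 2-fold or after quantile normalization, the compression correction, the mean over all CpGs each library lists, and the lists of choroid plexus genes, RNAs without poly(A) tails and cholesterol synthesis. The tests of explanations and the counts over other splits of the libraries were also set up after the patterns had been seen.

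Named genes follow a fixed rule. Per comparison they are the 6 largest log2 changes in each direction among genes that passed, had a mean of 5 RPKM in a group and did not overlap between groups, then up to 3 members of each list and direction with the smallest p, and always Fos, Arc, Npas4, Bdnf, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3. Some genes that this rule names are not reported here. The text gives the other always-named genes, the largest changes and examples of the list members. Named bins are the 5 largest differences in each direction among changed bins that overlap a peak, and named peaks the 5 replicated gains and losses with the highest score in the second pair of lists. The test was checked on simulated values with 200 genes changed in each of the comparisons, drawn over 14801 genes. For Bic/4AP against untreated it recovered 59.7% of 1.5-fold, 88.1% of 2-fold and 97.0% of 4-fold changes with 9 false calls. For TTX against untreated it recovered 70.1%, 89.6% and 100% with 9 false calls, and for Bic/4AP against TTX 62.7%, 88.1% and 100% with 4.

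Methylation was averaged over CpGs listed in all 3 libraries and over bins of 1 kb with at least 5 such CpGs, and a bin counted as changed at 20 points. Peaks overlapped at 1 bp or more. A replicated gain was a Bic/4AP peak present in both Bic/4AP lists and in no untreated list, and a loss the reverse. The gene table gives no strand, so distances run to the nearer end of a gene in place of its start, and a peak within 2 kb of an end is near a gene end. Links used 50 kb and 10000 random gene lists matched on mean expression, and peak classes used 10000 random sets of peaks of the same kind. Tables were handled with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

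Alternatives were a pseudocount of 0.1 and of 5, no filter on low values, a replicate block, a fit of the 6 libraries compared, limma-voom on the recovered whole reads, a 1.5-fold minimum, leaving out each library, quantile and cyclic loess normalization, bins of 500 bp and of 2 kb at 20 points, bins of 1 kb at 10 and at 30 points, overlap of 50%, stricter peak lists, each pair of lists alone, and distances of 10 and 100 kb. Other alternatives that need counts, and those that need coverage or a genome, including the motif search in gained peaks, were not run.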

Results

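The series asked how neuronal activity changes gene expression, CpG methylation and histone marks of enhancers in mouse hippocampal neurons. Neurons from embryonic day 17 hippocampus were cultured for 10 days. They were left untreated, silenced with tetrodotoxin (TTX, a blocker of voltage-gated sodium channels), or excited for 3 h with bicuculline, an antagonist of GABA-A receptors, together with 4-aminopyridine, a potassium channel blocker (Bic/4AP). RNA-seq was done on 3 libraries of each treatment from ICR mice. Bisulfite sequencing was done on 1 library of each treatment from C57BL/6 mice. ChIP-seq peak lists covered H3K27ac, a mark of active enhancers and promoters, in 2 untreated and 2 Bic/4AP samples of ICR mice. H3K4me1, a mark of enhancers, was covered in 2 untreated samples. The expression values gave back 12.6, 11.9 and 9.68 M reads for the TTX libraries, 5.63, 9.97 and 5.74 M for the untreated libraries and 4.52, 4.59 and 4.34 M for the Bic/4AP libraries. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Gene values below are mean RPKM ± SD with n = 3 libraries per group, log2 changes are on the log2(RPKM + 1) scale, and gene p-values are limma's with Benjamini-Hochberg adjustment.

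The first comparison asked what 3 h of Bic/4AP changed against untreated neurons. Transcription factor genes of the activity response were among the largest rises. Fosb, an AP-1 subunit, reached 108 ± 6.16 RPKM against 1.12 ± 0.29 (adjusted p = 2.57e-10), Fos reached 185 ± 8.87 against 9.76 ± 2.5 (adjusted p = 1.24e-09) and Npas4, an activity-dependent factor of neurons, reached 124 ± 8.94 against 8.5 ± 1.5 (adjusted p = 1.46e-09). Bdnf, which encodes a secreted neurotrophin, rose to 77.4 ± 0.726 against 23 ± 1.15, and Arc, which encodes a postsynaptic protein of AMPA receptor trafficking, rose to 61.9 ± 9.99 against 9.91 ± 1.67. Among the strongest falls were Kcnj13, a potassium channel gene of choroid plexus epithelium, at 0.386 ± 0.25 against 47.8 ± 9.75, and Tnfrsf25, a death receptor gene, at 0.237 ± 0.124 against 39.8 ± 7.88. Kcnj13 was also low with TTX, at 0.0404 RPKM, so its low value was not particular to Bic/4AP.

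Of 14801 genes tested, 4376 rose and 6297 fell with Bic/4AP. The 3 libraries of one group lay wholly apart from the 3 of the other for 10549 genes, or 71.3%, where chance gives 10%. The balance of rises and falls depended on scaling: 5741 rose and 4568 fell after quantile normalization, and 5300 rose and 5174 fell after cyclic loess normalization. With all 3 scalings together, 3200 genes rose and 4114 fell. At 2-fold or more, 490 rose and 2619 fell, or 446 and 1450 under all 3 scalings. The median log2 change of all genes was -0.12 as deposited, and quantile normalization shifted it by 0.18. Log2 changes of genes and lists in this comparison are therefore given relative to that median of -0.12, while the calls use the deposited scale. The median log2 change also depended on level, at -0.55 in the fourth decile of genes by mean RPKM and 0.44 in the top decile. Subtracting 1 median for all genes does not remove this dependence, so a relative change still includes the shift of genes of that level. The other largest changes were rises of Serpinb2, a plasminogen activator inhibitor gene (38 ± 14.2 against 0.875 ± 0.176), and Fndc9 (59.1 ± 4.66 against 3.47 ± 1.36). The microRNA gene Mir10b was listed at 0 in every untreated library and averaged 15.2 ± 7.88 with Bic/4AP. Mir377, Mir6516, Mir7080 and the small Cajal body RNA Scarna17 were listed at 0 in all Bic/4AP libraries against 43.9 ± 15.8, 41.1 ± 13.3, 37.3 ± 3.78 and 37.8 ± 4.12 RPKM untreated. Such short genes rest on few reads and can share them with a host gene.

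**Figure D1:**
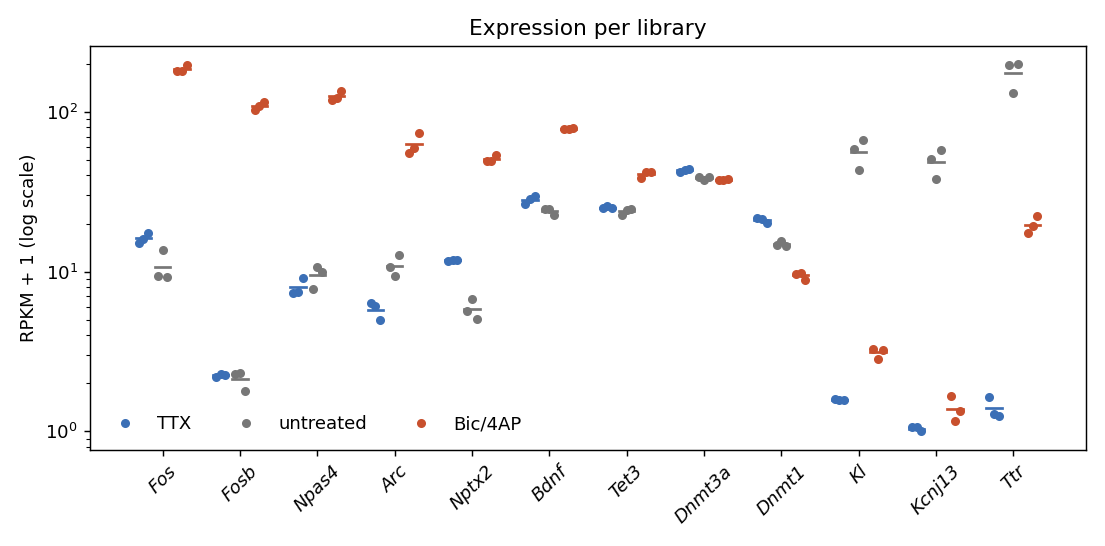
RPKM + 1 on a log axis in each library for 12 named genes, with points for single libraries of the TTX, untreated and Bic/4AP groups. Fos lies between 179 and 195 in the Bic/4AP libraries and between 8.24 and 12.6 RPKM in the untreated libraries.

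Most of the fast activity genes rose. Of 33 rapid activity genes, 31 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. The median relative log2 change was 2.24 (limma camera adjusted p = 3.17e-17, adjusted p = 0.173 with an estimated correlation). Junb rose to 63.5 ± 1.86 RPKM against 7.39 ± 0.688 and Egr3, a zinc finger factor, to 76 ± 1.98 against 16.3 ± 1.02, with relative log2 changes of 3.07 and 2.28. Srf, the serum response factor gene, was the member that fell, at 8.07 ± 0.376 against 10.8 ± 1.16, and this call was lost under both other scalings (log2 0.13 and 0.08). Of 33 late activity genes, 29 rose and 1 fell, or 30 and 1 adjusted over the list alone (camera adjusted p = 6.10e-15, adjusted p = 0.167 with an estimated correlation). Nptx2, a secreted pentraxin of excitatory synapses, reached 50.1 ± 2.56 against 4.81 ± 0.864 and Tiparp, an ADP-ribosyltransferase gene, 59.7 ± 4.42 against 13.6 ± 1.21. Of 18 feedback genes of MAP kinase signalling, 15 rose and 2 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 4.39e-06, adjusted p = 0.251 with an estimated correlation). After quantile normalization 16 of them rose and 0 fell. The dual-specificity phosphatase genes Dusp14 and Dusp4 rose to 91.5 ± 6.08 against 21.3 ± 1.62 and 73.2 ± 4.8 against 18.4 ± 2.63, and Errfi1, an inhibitor of the EGF receptor, to 90.8 ± 9.34 against 20.3 ± 2.36.

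Excitatory synapse genes, the subject of the series, moved both ways. Of 76 tested, 23 rose, 38 fell and 15 did not pass, with the same counts adjusted over the list alone. Camera gave adjusted p = 0.746; the list was called lower after quantile normalization (20 up, 39 down, adjusted p = 0.0102) and after loess (20 up, 41 down, adjusted p = 0.0409). Slc17a6, which encodes a vesicular glutamate transporter, rose to 48.4 ± 2.21 RPKM against 16.1 ± 2.6 and the synaptic adhesion gene Lrrc4 to 49.5 ± 3.54 against 23.9 ± 2.01. Grm7, a metabotropic glutamate receptor gene, fell to 12.8 ± 1.41 against 43.3 ± 3.56, Cacng8, an auxiliary AMPA receptor subunit gene, to 7.27 ± 0.256 against 35.4 ± 6.54, and the kainate receptor gene Grik4 to 12.2 ± 0.3002 against 33 ± 3.96. Of 26 inhibitory synapse genes, 17 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.00037, adjusted p = 0.227 with an estimated correlation). That call was lost after quantile (12 up, 7 down, adjusted p = 0.615) and loess normalization (13 up, 9 down, adjusted p = 0.373). Gad2, a GABA-synthesizing enzyme gene, rose to 111 ± 6.55 against 62.3 ± 4.49, while Shisa7, which encodes an auxiliary receptor protein, fell to 24.7 ± 1.73 against 37.9 ± 2.67. Of 12 peptide and calcium-binding genes of interneurons, 11 rose and 1, Nos1, fell, also adjusted over the list alone (camera adjusted p = 0.000101, adjusted p = 0.173 with an estimated correlation). Npy, which encodes neuropeptide Y, rose to 94.3 ± 2.08 against 52.8 ± 1.81.

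Genes of DNA methylation and demethylation went both ways: 9 of 23 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.622, pointing up, with a median log2 change of 0.00 and a mean of -0.12 as deposited). Dnmt1, the maintenance methyltransferase gene, fell to 8.46 ± 0.552 RPKM against 13.9 ± 0.635 (relative log2 change -0.53, or -0.20 after quantile and -0.28 after loess normalization, adjusted p = 1.10e-05). Dnmt3a, the main de novo methyltransferase gene of neurons, was at 36.7 ± 0.526 against 37.7 ± 0.815 (log2 change -0.04 as deposited and 0.09 relative to the median gene, adjusted p = 0.488), and it was called lower after quantile (-0.18) and loess normalization (-0.24). The demethylating dioxygenase genes Tet3 and Tet2 rose to 40 ± 1.96 against 22.9 ± 1.03 and 32.4 ± 0.229 against 23.6 ± 1.2. Tet1 was at 17.3 ± 1.3 against 17.4 ± 2.9 (adjusted p = 0.986), and was called higher only after loess normalization (0.26). Dnmt3b stayed below the expression filter, with values of 0.451, 0.672 and 0.564 RPKM untreated and 0.0511, 0.101 and 0.0533 with Bic/4AP. Of 23 histone acetylation genes, 1 rose and 15 fell, also adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.173 with an estimated correlation). After quantile normalization 3 rose and 15 fell. The deacetylase gene Hdac7 fell to 0.962 ± 0.103 against 13.3 ± 2.41, the acetyltransferase gene Kat2a to 17 ± 0.576 against 29.6 ± 1.16, and Hdac9 was the member that rose, to 48.3 ± 0.576 against 33.7 ± 2.66. Of 45 voltage-gated channel genes, 10 rose and 24 fell, also adjusted over the list alone (camera adjusted p = 0.251). Cacna1h, a T-type calcium channel gene, fell to 5.8 ± 0.96 against 41 ± 7.31. Of 27 stress and cell death genes, 15 rose and 6 fell, or 15 and 7 adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.173 with an estimated correlation). Dnajb1, a heat shock cochaperone gene, rose to 55.1 ± 7.19 against 23.4 ± 1.87 and Bax, a proapoptotic gene, fell to 18.4 ± 0.153 against 28.9 ± 2.3.

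Markers of cell types were measured in the same libraries. General neuron markers were higher for 10 of 12 genes and lower for 1, Rbfox3 (camera adjusted p = 0.00037, adjusted p = 0.306 with an estimated correlation), but 5 rose and 3 fell after quantile and 3 rose and 7 fell after loess normalization. Astrocyte markers rose for 9 of 13 and fell for 1 (camera adjusted p = 0.0101, adjusted p = 0.38 with an estimated correlation), with Sox9 at 22.6 ± 1.46 RPKM against 10.7 ± 1.74. Progenitor and cycling genes rose for 5 of 8 and fell for 0 (camera adjusted p = 0.0297, adjusted p = 0.38 with an estimated correlation), with Sox2 at 22.9 ± 1.55 against 10.8 ± 0.888. Oligodendrocyte lineage genes rose for 1 and fell for 4 of 8 (4 and 3 after quantile, 4 and 3 after loess normalization, camera adjusted p = 0.746). Microglia and macrophage genes rose for 4 and fell for 1 of 9 (7 and 0, 6 and 0 under those scalings, camera adjusted p = 0.197). Vascular, mural and fibroblast genes rose for 4 and fell for 3 of 10 (7 and 0 under both scalings, camera adjusted p = 0.303). Adjusted over the list alone, 4 microglia genes rose and 0 fell, and the other marker counts were the same. Choroid plexus genes, a list added after the data were seen, fell for 22 of 24 and rose for 1 (median relative log2 change -3.53, camera adjusted p = 2.03e-09, adjusted p = 0.138 with an estimated correlation). RNAs without poly(A) tails, also added, fell for 14 of 14 (median -3.69, camera adjusted p = 6.83e-06, adjusted p = 0.138 with an estimated correlation). Both groups were high in the untreated libraries, against which every gene group of this comparison was measured.

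The second comparison asked what silencing with TTX changed against untreated neurons. Genes of the choroid plexus had some of the largest falls: Ttr, which encodes the thyroid hormone carrier transthyretin, was at 0.393 ± 0.221 RPKM against 175 ± 38.2 (adjusted p = 4.72e-10), Kl, which encodes klotho, at 0.576 ± 0.0231 against 55.1 ± 11.8 and Kcnj13 at 0.0404 ± 0.035 against 47.8 ± 9.75. Small nuclear and nucleolar RNAs without poly(A) tails fell with them, as Scarna10 at 1.25 ± 0.18 against 224 ± 51.5 and Snora74a at 0.907 ± 0.455 against 68.5 ± 17.3. Arc fell to 4.79 ± 0.707 against 9.91 ± 1.67 (adjusted p = 0.000137), while Fos was higher with TTX at 15.2 ± 1.24 against 9.76 ± 2.5 (adjusted p = 0.00111). Vgf, which encodes a secreted neuropeptide precursor, rose to 45.9 ± 2.57 against 18.2 ± 3.05.

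In all, 6008 genes rose and 3483 fell with TTX. Quantile normalization gave 5521 and 4724 and loess normalization 4553 and 5241, so the side with more genes changed with the scaling, and 4247 genes rose and 3222 fell under all 3 scalings. The libraries of the groups lay wholly apart for 10300 genes, or 69.6% where chance gives 10%, and 901 rose and 974 fell by 2-fold or more, or 485 and 823 under all 3 scalings. The median log2 change of all genes was 0.13 as deposited, 0.05 after quantile and -0.03 after loess normalization. Log2 changes in this comparison are as deposited unless given relative to the median gene. Of the largest rises, Tcap, a muscle sarcomere gene, reached 14.2 ± 0.659 RPKM against 1.27 ± 0.628, S100a4, a calcium-binding protein gene, 9.96 ± 0.744 against 0.572 ± 0.517, Nupr1, a stress-induced nuclear protein gene, 19 ± 3.21 against 2.14 ± 0.784, and Crct1 8.16 ± 1.95 against 0.212 ± 0.255. Rps4l rose to 21.7 ± 2.68 against 3.85 ± 1.04 and Snord104 to 6.65 ± 2.85 against 0.458 ± 0.793, and both can share reads with related or overlapping genes. Scarna6 and Snord17 fell to 0.351 ± 0.324 against 96.7 ± 25.4 and 0.538 ± 0.576 against 73.6 ± 13.3.

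Activity genes did not fall together with TTX. Of 33 rapid activity genes, 26 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.00434, adjusted p = 0.675 with an estimated correlation). Junb was at 15.3 ± 0.849 RPKM against 7.39 ± 0.688 and Egr4, a zinc finger factor gene, at 12.3 ± 0.771 against 3.93 ± 0.942, while Arc, Arf4 and Per1 were the members that fell. Per1, a clock gene, was at 18.3 ± 0.558 against 20.9 ± 1.49 (adjusted p = 0.0278), a call lost when any TTX library or untreated library 2 or 3 was left out (log2 -0.15 to -0.20). Npas4 was at 6.96 ± 0.965 against 8.5 ± 1.5 (log2 change -0.25, -0.38 relative to the median gene, adjusted p = 0.0796), and it was called lower after quantile (-0.41) and loess normalization (-0.51) and without TTX library 3 (-0.35) or untreated library 1 (-0.38). Bdnf was higher at 27.2 ± 1.5 against 23 ± 1.15 (adjusted p = 0.00299), a call lost after quantile normalization (0.06). Of 33 late activity genes, 17 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.571), with 14 up and 11 down after loess normalization. Homer1, a postsynaptic scaffold gene, fell to 24.1 ± 0.271 against 30.1 ± 0.957. Of 18 MAP kinase feedback genes, 15 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00852, adjusted p = 0.675 with an estimated correlation), and 14 rose and 3 fell after quantile normalization. Spry4, a Sprouty inhibitor gene, rose to 21.3 ± 1.13 against 7.84 ± 2.76.

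Excitatory synapse genes fell more often than they rose with TTX: 37 of 76 fell and 19 rose, or 38 and 19 adjusted over the list alone (camera adjusted p = 0.00434, adjusted p = 0.528 with an estimated correlation). Loess normalization gave 47 down and 13 up. The median log2 change of all genes with TTX also fell with gene length. It went from 0.27 in the shortest of 5 length classes to -0.05 in the longest, and was -0.07 in the top decile by level. Whether length or level accounts for the fall of this list was not tested. Grin2a, an NMDA receptor subunit gene, fell to 25.4 ± 0.809 RPKM against 53.3 ± 7.32, the neurexin gene Nrxn3 to 22.2 ± 0.844 against 40.7 ± 3.65 and the adhesion gene Lrrtm4 to 12.6 ± 0.507 against 24.8 ± 1.56, while the scaffold gene Dlgap3 rose to 41.5 ± 1.88 against 26.7 ± 0.754. Of 26 inhibitory synapse genes, 6 rose and 12 fell (camera adjusted p = 0.0946), with Slc32a1, the vesicular GABA transporter gene, at 36.6 ± 1.8 against 14.8 ± 4.36 and Shisa7 at 24 ± 0.417 against 37.9 ± 2.67. Interneuron peptide genes rose for 9 of 12 and fell for 1 (camera adjusted p = 0.0946), with Cck, the cholecystokinin gene, at 46.2 ± 2.46 against 19.4 ± 1.59. Voltage-gated channel genes rose for 15 and fell for 17 of 45 (camera adjusted p = 0.192), and 13 rose and 25 fell after quantile and 9 rose and 26 fell after loess normalization. The calcium channel genes Cacna1e and Cacna1a fell to 19.2 ± 0.534 against 45.6 ± 5.64 and 23.1 ± 0.545 against 46.6 ± 7.51, and the pacemaker channel gene Hcn2 rose to 36 ± 0.923 against 17.4 ± 2.66. The counts of these 3 lists were the same adjusted over the list alone.

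DNA methylation genes rose for 9 and fell for 3 of 23 with TTX (camera adjusted p = 0.886), but 8 rose and 9 fell after quantile and 3 rose and 9 fell after loess normalization. Dnmt1 rose to 20 ± 0.832 RPKM against 13.9 ± 0.635 (log2 change 0.50, or 0.31 after quantile and 0.18 after loess normalization, adjusted p = 0.000176) and Tet2 fell to 18 ± 0.458 against 23.6 ± 1.2 (adjusted p = 0.000119). Dnmt3a was higher at 42 ± 0.917 against 37.7 ± 0.815 (adjusted p = 0.0117), a call lost after loess normalization. Tet1 and Tet3 did not pass, with log2 changes of -0.01 and 0.08, or -0.14 and -0.05 relative to the median gene, but Tet1 was called lower under both other scalings (-0.28 and -0.30) and Tet3 after quantile normalization (-0.14). Dnmt3b values were 0.384, 0.234 and 0.454 RPKM with TTX. Histone acetylation genes rose for 8 and fell for 7 of 23 (7 and 13 after quantile, 5 and 13 after loess normalization, camera adjusted p = 0.629), with Hdac11 at 39.8 ± 0.85 against 26.2 ± 1.45 and Crebbp, a coactivator acetyltransferase gene, at 25.4 ± 0.983 against 32.9 ± 1.55. Stress and death genes rose for 17 of 27 and fell for 2 (camera adjusted p = 0.0353, adjusted p = 0.528 with an estimated correlation). Ddit3, a factor of the unfolded protein response, rose to 28 ± 1.25 against 12.7 ± 0.842. These counts were the same adjusted over the list alone.

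With TTX, astrocyte markers rose for 8 of 13 and fell for 2, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.571), with Gfap at 27.9 ± 3.43 RPKM against 10.2 ± 2.27. Oligodendrocyte lineage genes rose for 5 and fell for 3 of 8 (camera adjusted p = 0.698), with the precursor marker Olig1 at 23.6 ± 2.22 against 6.99 ± 2.38. Microglia genes rose for 4 of 9 and fell for 0, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.571). Vascular, mural and fibroblast genes rose for 5 of 10 and fell for 0 (4 and 1, 4 and 2 under the other scalings, camera adjusted p = 0.571), with the collagen gene Col1a1 at 11.6 ± 1.05 against 1.99 ± 0.65. Progenitor genes rose for 3 of 8 and fell for 0 (camera adjusted p = 0.571). Neuron markers rose for 4 and fell for 5 of 12 (median log2 change 0.02, mean -0.01, camera pointing down with adjusted p = 0.571), but 7 rose and 4 fell after quantile and 6 rose and 4 fell after loess normalization. Counts given once were the same adjusted over the list alone. All 24 choroid plexus genes fell (median log2 change -3.61, -3.74 relative to the median gene, camera adjusted p = 2.08e-21, adjusted p = 0.0415 with an estimated correlation), and so did all 14 RNAs without poly(A) tails (median -4.50 and -4.63, camera adjusted p = 3.17e-13, adjusted p = 0.023). The p-values of both lists were adjusted over only the 3 lists added after the data were seen.

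The third comparison set excited against silenced neurons, the widest contrast of activity by treatment, and it sets no value against the untreated libraries. Fosb reached 108 ± 6.16 RPKM against 1.24 ± 0.0423 (adjusted p = 3.10e-10), Npas4 124 ± 8.94 against 6.96 ± 0.965, Fos 185 ± 8.87 against 15.2 ± 1.24, Arc 61.9 ± 9.99 against 4.79 ± 0.707 and Bdnf 77.4 ± 0.726 against 27.2 ± 1.5. Homer1 reached 72.1 ± 2.51 against 24.1 ± 0.271 and Nr4a1, an orphan nuclear receptor gene, 79.8 ± 4.87 against 14.6 ± 0.601. Nupr1 fell to 1.53 ± 1.1 against 19 ± 3.21 and Cabp7, a calcium-binding protein gene, to 2.001 ± 1.07 against 22.6 ± 0.467.

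In all, 3508 genes rose and 7861 fell against TTX, with 4986 up and 5351 down after quantile and 5134 up and 5290 down after loess normalization. Under all 3 scalings, 2810 rose and 4564 fell. At 2-fold or more, 553 rose and 3026 fell, or 465 and 688 under all 3 scalings. The groups lay wholly apart for 12067 genes, or 81.5% where chance gives 10%. The median log2 change of all genes was -0.33, quantile normalization shifted it by 0.30, and log2 changes in this comparison are given relative to -0.33. The median log2 change depended on the level of the gene: it was -0.89 in the fourth decile of genes by mean RPKM and 0.49 in the top decile. Further large rises were those of Serpinb2 (38 ± 14.2 against 0.727 ± 0.04005), Ttr (18.7 ± 2.46 against 0.393 ± 0.221) and the microRNA genes Mir376b (15.4 ± 2.81 against 0.343 ± 0.594) and Mir1954 (15.8 ± 4.12 against 0.375 ± 0.649). Further large falls were those of Bcdin3d (0.526 ± 0.17 against 10.1 ± 1.49), Gpatch4 (1.23 ± 0.533 against 14.7 ± 1.32) and Nat9 (0.98 ± 0.369 against 12.8 ± 0.916), and Snord55 was listed at 0 in all Bic/4AP libraries against 6.04 ± 0.61 with TTX.

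**Figure D2:**
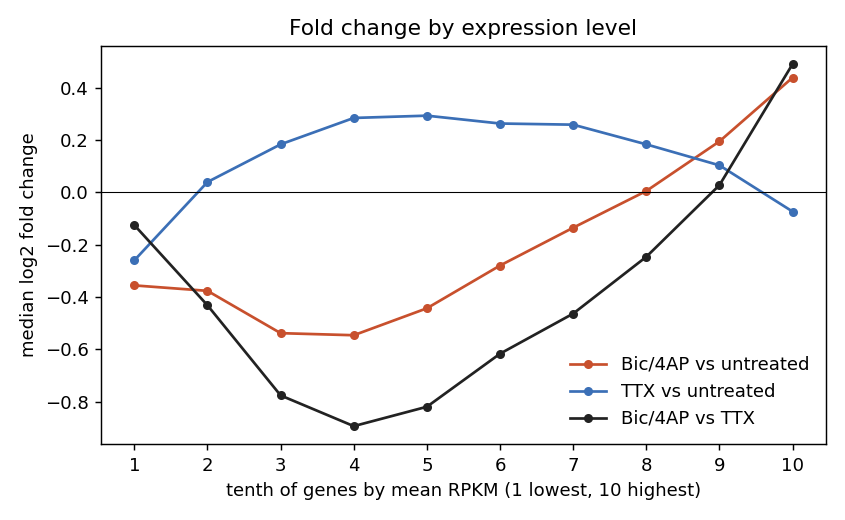
Median log2 fold change of genes in each decile of mean RPKM, from the lowest to the highest, for the 3 comparisons. Bic/4AP against TTX falls to -0.89 in the fourth decile and reaches 0.49 in the top decile, while TTX against untreated is -0.07 in the top decile.

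Of 33 rapid activity genes, 27 rose and 1 fell, also adjusted over the list alone (median relative log2 change 1.82, camera adjusted p = 1.33e-14, adjusted p = 0.257 with an estimated correlation). Of 33 late activity genes, 28 rose and 2, Plk3 and Sorcs3, fell, also adjusted over the list alone (camera adjusted p = 1.33e-14, adjusted p = 0.176 with an estimated correlation). Plk3 lost its call under both other scalings, and Sorcs3 was called higher under both (0.44 and 0.53). MAP kinase feedback genes rose for 11 of 18 and fell for 4, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.001005, adjusted p = 0.439 with an estimated correlation). Dusp14 reached 91.5 ± 6.08 RPKM against 32.1 ± 1.01 and Spry2, a Sprouty inhibitor gene, 87.1 ± 4.55 against 38.6 ± 2.8.

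Excitatory synapse genes rose for 28 and fell for 32 of 76, or 29 and 32 adjusted over the list alone (camera adjusted p = 0.0635), but 35 rose and 28 fell after quantile and 32 rose and 32 fell after loess normalization. The adhesion genes Lrrtm2 and Lrrc4c rose to 60.5 ± 2.24 RPKM against 30.8 ± 0.363 and 44.1 ± 1.69 against 21.2 ± 0.46, while Ephb2, an ephrin receptor gene, fell to 7.19 ± 0.607 against 23.8 ± 1.31 and Dlgap3 to 19.5 ± 0.749 against 41.5 ± 1.88. Inhibitory synapse genes rose for 16 of 26 and fell for 5, also adjusted over the list alone (camera adjusted p = 3.47e-05, adjusted p = 0.272 with an estimated correlation, 0.0981 after loess normalization). Interneuron peptide genes rose for 8 of 12 and fell for 2 (camera adjusted p = 0.0103, adjusted p = 0.348 with an estimated correlation). That call was lost after quantile (7 up, 5 down, adjusted p = 0.507) and loess normalization (7 up, 4 down, adjusted p = 0.437). Voltage-gated channel genes rose for 9 and fell for 28 of 45 (15 and 13 under both other scalings, camera adjusted p = 0.668). The potassium channel gene Kcng1 fell to 2.05 ± 0.288 against 19.8 ± 2.44.

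Dnmt1 fell to 8.46 ± 0.552 RPKM against 20 ± 0.832 (relative log2 change -0.82, or -0.51 after quantile and -0.45 after loess normalization, adjusted p = 1.03e-07) and Dnmt3a to 36.7 ± 0.526 against 42 ± 0.917 (log2 change -0.19, 0.14 relative to the median gene, -0.29 after quantile and -0.31 after loess normalization, adjusted p = 0.00243). Tet2 rose to 32.4 ± 0.229 against 18 ± 0.458 and Tet3 to 40 ± 1.96 against 24.2 ± 0.542. Tet1 was at 17.3 ± 1.3 against 17.2 ± 0.57 (adjusted p = 0.924) and was called higher under both other scalings (0.50 and 0.56). The DNA methylation list had 8 members up and 13 down of 23 (9 and 7 after quantile, 10 and 7 after loess normalization, camera adjusted p = 0.668). Histone acetylation genes rose for 3 and fell for 15 of 23 (5 and 12 under both other scalings, camera adjusted p = 0.146), with Kat2a at 17 ± 0.576 against 36.3 ± 0.472. Stress and death genes rose for 10 and fell for 11 of 27 (camera adjusted p = 0.342), with Ddit3 at 10 ± 1.3 against 28 ± 1.25 and Bbc3, a p53 target gene, at 0.635 ± 0.247 against 7.11 ± 0.954. Counts of these and the preceding lists given once were the same adjusted over the list alone.

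Against TTX, neuron markers rose for 9 of 12 and fell for 1 (camera adjusted p = 0.000252, adjusted p = 0.348 with an estimated correlation), but 4 rose and 5 fell after quantile (adjusted p = 0.868) and 1 rose and 5 fell after loess normalization (adjusted p = 0.228). Rbfox3, the marker that fell, was called higher after quantile normalization (0.21). Astrocyte genes rose for 6 and fell for 5 of 13 (7 and 3 under both other scalings, camera adjusted p = 0.146). Oligodendrocyte lineage genes rose for 0 and fell for 5 of 8 (1 and 3 under both, camera adjusted p = 0.404), with Mbp, a myelin gene, at 4.15 ± 0.417 RPKM against 12.4 ± 0.992. Microglia genes rose for 2 and fell for 2 of 9 (5 and 1 under both, camera adjusted p = 0.407). Vascular, mural and fibroblast genes rose for 3 and fell for 5 of 10 (5 and 2 after quantile, 4 and 2 after loess normalization, camera adjusted p = 0.827). Progenitor genes rose for 3 and fell for 1 of 8, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.164), and the counts of the neuron, astrocyte, oligodendrocyte lineage, microglia and vascular lists were the same adjusted over the list alone. Camera, which compares a list with all other genes, pointed up for excitatory synapse, DNA methylation, stress, microglia and vascular genes although their median log2 changes as deposited were -0.01, -0.23, -0.12, -0.04 and -0.41, and for astrocyte genes with a median of 0.08 and a mean of -0.02. Choroid plexus genes rose for 6 and fell for 5 of 24, or 6 and 4 adjusted over the list alone (9 and 1 after quantile, 15 and 1 after loess normalization, camera adjusted p = 0.0354, adjusted p = 0.551 with an estimated correlation). RNAs without poly(A) tails rose for 9 of 14 and fell for 1 (camera adjusted p = 0.00569, adjusted p = 0.442 with an estimated correlation, 0.135 after loess normalization).

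Genes that rose with Bic/4AP and genes that changed with TTX were then compared. Of the genes tested, 1775 rose and 2245 fell in both comparisons with untreated, 852 rose with Bic/4AP and fell with TTX, and 2007 fell with Bic/4AP and rose with TTX. These numbers depended on scaling: after quantile normalization they were 2809, 2583, 1093 and 819, and after loess normalization 2031, 2874, 1295 and 849. On the deposited scale, independent lists of these sizes would share 1776, 1482, 1030 and 2556 genes. Unchanged groups were simulated 20 times, with all 9 libraries drawn around the untreated means, and shared 0 genes. Almost no gene can pass in both comparisons of such groups, so this 0 is no benchmark for the shared counts. The log2 changes correlated across genes with r = 0.555 (0.652 after quantile normalization), against 0.499 with unchanged groups, and their covariance was 0.384 (0.426 after quantile normalization) against 0.0139. Genes are not independent replicates. The 3 untreated libraries cannot be split into parts of 2, and part of the shared change may come from the libraries both comparisons use.

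CpG methylation was compared over the 15007037 CpGs listed in all 3 libraries. The mean level was 73.7% untreated, 73.7% with TTX and 73.6% with Bic/4AP. The level with Bic/4AP differed by -0.153 points from untreated and by -0.128 points from TTX, and the level with TTX differed by -0.0243 points from untreated. Over all CpGs each library lists, these differences were -0.0418, -0.169 and 0.128 points, so that of TTX changed direction. All 19 autosomes and chromosome X (-0.177 points) had a lower mean with Bic/4AP than untreated. Chromosome Y and the mitochondrial genome had a higher one (0.145 and 0.0859 points). Chromosomes of 1 library are not replicates. With TTX the mean over autosomes was also lower than untreated (-0.0225 points). There is 1 library per treatment, so no difference has a replicate check, and the depth behind each level is unknown.

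Of 1194478 bins of 1 kb with at least 5 CpGs, 1090 were at least 20 points higher with Bic/4AP than untreated and 1279 at least 20 points lower, together 0.198% of bins. TTX against untreated gave 1379 higher and 1294 lower bins, and Bic/4AP against TTX 1048 and 1197. The changed bins that overlap a histone mark peak and differed most are named here in mm10 coordinates. A bin inside Epha3, an ephrin receptor gene (chromosome 16, 63621000 to 63621999, 6 CpGs), was at 43.3% untreated, 45.7% with TTX and 73.7% with Bic/4AP. A bin inside Thbs2, a thrombospondin gene (chromosome 17, 14668000 to 14668999, 5 CpGs), was at 70.1%, 87.7% and 100%. Bins outside genes lay nearest to Lsamp (chromosome 16, 39751000 to 39751999), Dgkb (chromosome 12, 37820000 to 37820999) and Tmcc3 (chromosome 10, 94595000 to 94595999) and were higher by 32.9, 32.2 and 30.04 points. Lsamp, Dgkb and Tmcc3 lay 232255, 59170 and 4046 bp away. A bin inside Rev1, a translesion polymerase gene (chromosome 1, 38099000 to 38099999, 5 CpGs), was at 98.3% untreated, 86.5% with TTX and 62% with Bic/4AP. A bin inside Ednra, an endothelin receptor gene (chromosome 8, 77683000 to 77683999, 5 CpGs), was at 81.7%, 76.5% and 50.6%. Bins outside genes nearest to N6amt1 (chromosome 16, 86933000 to 86933999), Gk2 (chromosome 5, 97634000 to 97634999) and Ift57 (chromosome 16, 49806000 to 49806999) fell by 35.8, 32.6 and 31.1 points. N6amt1, Gk2 and Ift57 lay 420186, 176977 and 40874 bp away. Changed bins held a median of 5 CpGs and all bins a median of 8.

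The H3K27ac lists addressed which regions gained or lost the mark with Bic/4AP. The first pair of lists held 4846 peaks untreated and 7721 with Bic/4AP, and the second pair 49701 and 55035. Of untreated peaks, 59.6% overlapped a Bic/4AP peak in the first pair and 56.3% in the second, and of Bic/4AP peaks 33.3% and 48.7% overlapped an untreated peak. Within a treatment, 88.7% of the shorter untreated list lay in the longer one, and 93.3% of the shorter Bic/4AP list. Gains seen in both pairs numbered 1009, of which 51.6% lay within 2 kb of a gene end, and losses seen in both pairs numbered 134, of which 15.7% did. The Bic/4AP lists were the longer ones, and with equally many top-scoring peaks per list gains numbered 493 and losses 381. Of all peaks, 54.4% of the first and 18.1% of the second Bic/4AP list lay within 2 kb of a gene end, and 41.8% and 16.1% of the untreated lists. The H3K4me1 lists held 21512 and 19102 peaks and shared 22.04% and 24.7% of them. The peak score is the authors' and was used only inside a list.

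The highest-scoring gains lay across a gene end at Srsf11 and Lrrc40 (chromosome 3, 158030252 to 158037442) and inside Cacna1a (chromosome 8, 84493044 to 84500213), Msi2 (chromosome 11, 88581435 to 88589535), Rgs7 (chromosome 1, 175095946 to 175101073) and R3hdm1 (chromosome 1, 128124281 to 128131528). Cacna1a, a calcium channel gene, was lower in RNA with Bic/4AP (19.3 against 46.6 RPKM, adjusted p = 3.24e-07), and Msi2, which encodes an RNA-binding protein, was higher (44.5 against 30.2 RPKM, adjusted p = 2.52e-06). The gains inside Cacna1a and Msi2 lay 140038 and 128771 bp from the nearest gene end, beyond the 50 kb used for links, so these peaks enter no link. Srsf11 was lower (35.5 against 41.9 RPKM, adjusted p = 0.0366), R3hdm1 was higher (73.9 against 58.0 RPKM, adjusted p = 0.00167), and Rgs7 was at 34.5 against 37.6 RPKM (adjusted p = 0.0591). The highest-scoring losses lay inside Skap2 (chromosome 6, 51876942 to 51886335) and Rfc1 (chromosome 5, 65304082 to 65307286) and nearest to Armc1 (chromosome 3, 18711404 to 18717053), Zbtb18 (chromosome 1, 177570940 to 177576406) and Kynu (chromosome 2, 43689300 to 43693752). Kynu lay 6252 bp from its peak, but Zbtb18 lay 120176 bp and Armc1 414349 bp away, beyond the 50 kb used for links. Rfc1, a replication factor gene, was lower in RNA (6.37 against 14.2 RPKM, adjusted p = 5.9e-07), as was Skap2 (4.98 against 7.27 RPKM, adjusted p = 0.00663), while Armc1 was higher (55.7 against 48.1 RPKM, adjusted p = 0.00145) and Zbtb18 was at 69.5 against 64.2 RPKM (adjusted p = 0.138). Kynu was not among the genes tested.

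Gains and losses were set beside the RNA changes of Bic/4AP against untreated, for 13609 genes with coordinates. A replicated gain lay within 50 kb of an end of 13.2% of risen genes, and random gene lists matched on mean expression had a median of 13.5% (percentile 17.3). A replicated loss lay within 50 kb of 1.66% of fallen genes against a random median of 1.34% (percentile 99.9). Fallen genes had gains at 13.8% (percentile 82.01) and risen genes losses at 1.10% (percentile 3.19). Of 33 rapid activity genes, 6 had a gain, namely Cyr61, Egr1, Fosb, Gadd45b, Ier5 and Per1. Of 18 MAP kinase feedback genes 6 had one, namely Dusp6, Dusp8, Dusp10, Errfi1, Spred3 and Spry4. Of 76 excitatory synapse genes 5 had one, namely Bai1, Grik3, Grin1, Grin2d and Grm4. Of 33 late activity genes 6 had one, of 23 histone acetylation genes 5, and of 27 stress and death genes 5, and of all genes with coordinates 13.4% did. The lists of interneuron peptides and of neuron, astrocyte, oligodendrocyte lineage and vascular markers had 0. The shares of these lists were not tested against that of all genes. Genes are not independent replicates, and these percentiles describe the lists at hand.

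Methylation at the peaks asked whether enhancers with and without the mark changed with Bic/4AP. Distal peaks present with Bic/4AP alone were at 74.4% untreated and 74.2% with Bic/4AP, a difference of -0.217 points (percentile 20.6 of 10000 random sets of distal peaks). Distal peaks present in both treatments were at 60.7% and 60.5% (percentile 29.3) and those untreated alone at 65.8% and 65.7% (percentile 92.6). With TTX minus untreated, distal peaks in both differed by -0.0915 points (percentile 0.72), those untreated alone by 0.123 points (percentile 99.9) and those with Bic/4AP alone by -0.0317 points (percentile 28.8). At the 413 distal replicated gains the level differed by 0.169 points (percentile 91.6), and at the 79 distal losses by -0.0107 points (percentile 61.6). Near gene ends, peaks in both treatments differed by -0.0587 points (percentile 98.1) and peaks untreated alone by -0.296 points (percentile 0.98), but at 50% overlap the percentiles were 91.7 and 6.7. The 312 distal peaks nearest to an excitatory synapse gene were at 67.3% untreated and 67.4% with Bic/4AP, a difference of 0.103 points (percentile 83.3). Those nearest to inhibitory synapse, rapid activity and late activity genes differed by -0.303, -0.0846 and -0.00379 points (percentiles 42.2, 55.7 and 64.2). At distal H3K4me1 peaks without H3K27ac the difference was -0.213 points (percentile 46.04). These percentiles measure the spread over peaks and not between libraries, of which there is 1 per treatment. A percentile near 0 or 100 is therefore no evidence of a treatment effect. The peaks came from ICR mice and the methylation from C57BL/6 mice.

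**Figure D3:**
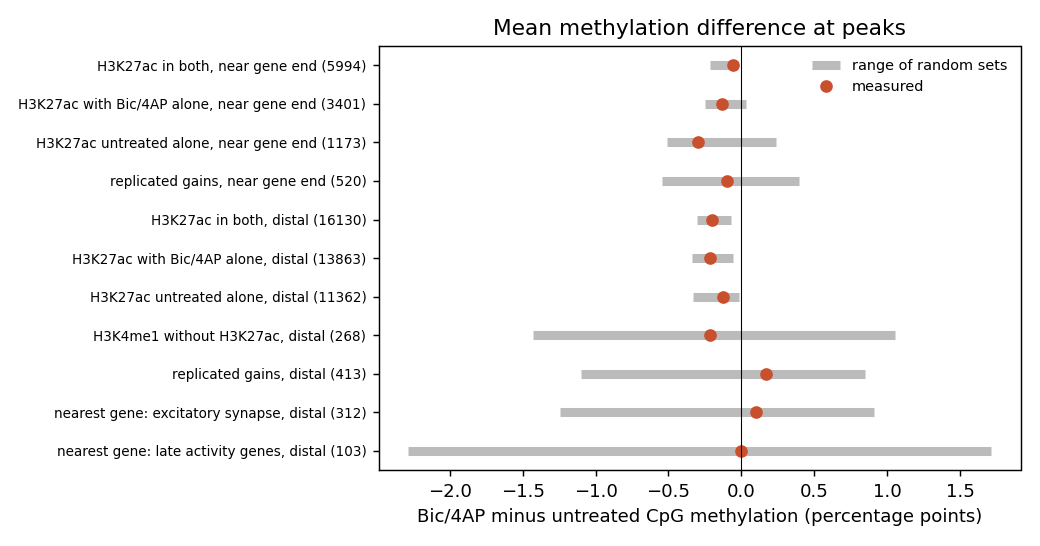
Methylation with Bic/4AP minus untreated, in percentage points, for each class of peaks, with the range of 10000 random sets of as many peaks of the same kind. Distal peaks with Bic/4AP alone lie at -0.217 points and distal replicated gains at 0.169 points, both inside the range of their random sets (-0.338 to -0.0595 and -1.10 to 0.848).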

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

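Quantile and cyclic loess normalization, the 2-fold and quantile-based links, the compression correction and the mean over all listed CpGs were chosen after the results were seen, and the other alternatives were planned. Of the alternatives that need read counts, limma-voom alone was run, on the recovered whole reads. Another size factor, another count test and a count filter were not run. Coverage minimums, read weighting and motif windows were not run because the methylation values carry no coverage and no genome is at hand. Lower depth limits genes of few reads, and the depth of methylation is unknown. Unless a value shows it, the cause of a change below was not tested.

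The counts of changed genes stayed within 1.5 times under both pseudocounts, no filter, the 6-library fit and limma-voom on recovered reads, which called 10095, 9962 and 11377 genes for Bic/4AP against untreated, TTX against untreated and Bic/4AP against TTX. Leaving out 1 library gave 10087 to 10881, 8314 to 10108 and 10563 to 10991 genes. The replicate numbers do not pair the libraries: the correlation of deviations ran from -0.173 to 0.0435 for libraries of the same number and from -0.129 to 0.208 for other pairs. The replicate block called 10616, 9345 and 11315 genes and changed the call in none of 57 list tests. Over named genes, leaving out 1 library kept direction and call in 1873 of 1938 cases, with 62 calls lost, 3 made and 0 turned.

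A 1.5-fold minimum, which by construction calls fewer genes, left 5967 changed and 1670 higher genes for Bic/4AP against untreated, 4574 changed, 2938 higher and 1636 lower for TTX against untreated, and 7281 changed and 1700 higher for Bic/4AP against TTX. It left 384 genes higher in both comparisons with untreated, 41 higher with Bic/4AP and lower with TTX, 464 the reverse and 1400 lower in both. Quantile normalization gave 2809 genes higher in both and 819 lower with Bic/4AP and higher with TTX, and loess gave 1295 higher with Bic/4AP and lower with TTX, 849 the reverse and 5241 genes lower with TTX than untreated.

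With an estimated correlation 26 list calls were lost and 2 held. The 2 were those of choroid plexus genes and of RNAs without poly(A) tails in TTX against untreated. Their camera p before adjustment was 0.0277 and 0.00767, adjusted over only the 3 lists added after the data were seen. Excitatory synapse genes, at 0.0354 before adjustment over 16 lists, lost their call. The calls that held therefore rest on the smaller adjustment and on lists drawn up from these data. For Bic/4AP against untreated the adjusted p became 0.173 for rapid activity, 0.167 for late activity, 0.251 for MAP kinase feedback, 0.227 for inhibitory synapse, 0.173 for interneuron peptides, 0.173 for histone acetylation, 0.173 for stress, 0.38 for astrocytes, 0.38 for progenitors, 0.306 for neuron markers, 0.138 for choroid plexus, 0.138 for RNAs without poly(A) tails and 0.138 for cholesterol synthesis. For TTX against untreated it became 0.675 for rapid activity, 0.675 for MAP kinase feedback, 0.528 for excitatory synapse and 0.528 for stress. For Bic/4AP against TTX it became 0.257 for rapid activity, 0.176 for late activity, 0.439 for MAP kinase feedback, 0.272 for inhibitory synapse, 0.348 for interneuron peptides, 0.348 for neuron markers, 0.551 for choroid plexus, 0.442 for RNAs without poly(A) tails and 0.518 for cholesterol synthesis.

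Fry called more lists, as it compares a list with no other genes. For Bic/4AP against untreated it gave 0.000168 for excitatory synapse, 2.64e-05 for channels and 0.000243 for oligodendrocyte lineage. For TTX against untreated it gave 0.00908 for late activity, 0.00137 for interneuron peptides, 0.0225 for DNA methylation, 0.0304 for astrocytes, 0.0262 for vascular cells, 0.0296 for progenitors and 0.00352 for cholesterol synthesis. For Bic/4AP against TTX it gave 6.85e-07 for histone acetylation, 8.52e-05 for channels and 8.90e-05 for oligodendrocyte lineage, and it lost the call of choroid plexus (0.196). Its direction was lower where camera gave higher for DNA methylation (0.0301 and 0.000822 against untreated and TTX), stress (0.00191 against TTX) and vascular cells (0.0319 against TTX), where camera's direction relative to other genes and the sign of the list mean also differ.

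Quantile normalization changed the camera calls for Bic/4AP against untreated (lost at 0.615 (inhibitory synapse) and 0.673 (neuron markers), and made at 0.0102 (excitatory synapse), 0.0469 (channels), 0.0164 (microglia) and 0.0392 (vascular cells)), for TTX against untreated (made at 0.0472 (inhibitory synapse) and 0.0472 (channels)), and for Bic/4AP against TTX (lost at 0.507 (interneuron peptides), 0.868 (neuron markers) and 0.86 (cholesterol synthesis)). Loess changed those for Bic/4AP against untreated (lost at 0.373 (inhibitory synapse) and 0.266 (neuron markers), and made at 0.0409 (excitatory synapse), 0.0264 (microglia) and 0.0452 (vascular cells)), for TTX against untreated (made at 0.0422 (interneuron peptides) and 0.0102 (cholesterol synthesis)), and for Bic/4AP against TTX (lost at 0.0981 (inhibitory synapse), 0.437 (interneuron peptides), 0.228 (neuron markers), 0.135 (RNAs without poly(A) tails) and 0.583 (cholesterol synthesis)). Among named genes in Bic/4AP against TTX, both scalings turned Sorcs3 (0.44 and 0.53), quantile turned Rbfox3 (0.21) and loess Rn45s (-0.65), whose reads are shared between ribosomal repeats.

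Gains and losses of H3K27ac numbered 656 and 84 with the upper part of each list by score, 493 and 381 with equally many top peaks, 5147 and 1960 in the first pair and 28227 and 21733 in the second. In shares against the random median, gains lay near 71.0% of risen genes with the second pair alone (72.5%, percentile 0.04). Losses lay near 0.462% of fallen genes at 10 kb (0.377%, percentile 91.4) and 1.67% of those at 2-fold (1.32%, percentile 94.4). Gains lay near 21.05% of fallen genes at 100 kb (20.02%, percentile 99.7) and 67.3% with the second pair (65.9%, percentile 99.95). Losses lay near 1.86% of risen genes at 100 kb (2.32%, percentile 0.16), 46.5% with the second pair (52.6%, percentile 0), 0.240% at 2-fold (1.2%, percentile 0.42) and 0.954% after quantile normalization (1.34%, percentile 0.07). Over all CpGs each library lists, mean methylation differed by -0.0418 points for Bic/4AP minus untreated and 0.128 for TTX minus untreated, where CpGs listed in all libraries gave a negative value. Higher and lower bins at 10 points numbered 34152 and 37709 (Bic/4AP minus untreated), 37114 and 37509 (TTX minus untreated) and 33505 and 36552 (Bic/4AP minus TTX). At 30 points they numbered 47 and 51, 49 and 37, and 36 and 49. Bins of 500 bp gave 1959 and 2335, 2303 and 2229, and 1848 and 2173, and bins of 2 kb 514 and 553, 566 and 607, and 477 and 479. Peaks in both treatments near gene ends differed by -0.0675 points at 50% overlap (percentile 91.7), and peaks untreated alone near gene ends by -0.219 points at 50% overlap (percentile 6.7) and -0.273 with the second pair (percentile 2.83).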

Other observations

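Chosen only after the results were seen were the counts over other splits of the libraries, the test of tailless RNA on choroid plexus genes, the test of the left and right part of methylation bins, the split of changed bins by whether they have a neighbour, the requirement that both compression fits leave the gap above 0.7, and the lists of choroid plexus, tailless RNA and cholesterol genes.

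Cholesterol synthesis genes, another such list, were tested in the same way. With Bic/4AP against untreated, 17 of 22 rose and 1, Lss, fell (median relative log2 change 0.58, or 0.15 after quantile and 0.16 after loess normalization, limma camera adjusted p = 6.83e-06, adjusted p = 0.138 with an estimated correlation), and 13 rose and 0 fell after quantile and 12 rose and 1 fell after loess normalization, with 10 higher under all 3 scalings. Ebp, a sterol isomerase gene, was at 25.4 ± 1.02 RPKM against 11.2 ± 2.4 and Sc5d, a sterol desaturase gene, at 82.5 ± 4.28 against 51.7 ± 0.756 (mean ± SD, n = 3). With TTX against untreated 11 rose and 5 fell (camera adjusted p = 0.163), with Mvk, the mevalonate kinase gene, at 45.9 ± 0.417 against 18 ± 3.97. With Bic/4AP against TTX 11 rose and 8 fell (camera adjusted p = 0.0105, adjusted p = 0.518 with an estimated correlation), but 7 rose and 9 fell after quantile and 7 rose and 11 fell after loess normalization. Adjusted over the list alone the counts were 17 up and 1 down, 11 up and 5 down, and 11 up and 8 down in this order of comparisons.

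Low and middle genes were lower and high genes higher with Bic/4AP than with TTX, with a gap of 1.38 in median log2 change between the top decile and the fourth decile of genes by level. Gene length is argued against as the cause, since the gap was at least 1.14 in each of 5 length classes. A compression of high values that grows with depth may contribute, as the TTX libraries were deeper (11.4 ± 1.54 M reads against 4.48 ± 0.130). A trend with depth was also seen inside groups. The deepest untreated library, 2, differed from libraries 1 and 3 by 0.189 in the fourth decile and -0.113 in the top decile. The shallowest TTX library, 3, differed from libraries 1 and 2 by -0.147 and 0.115. Each of these contrasts rests on 1 library. Removing the compression fitted inside the untreated group left a gap of 0.814, above the 0.7 set in advance as evidence against it, while the fit inside the TTX group left 0.549, so the outcome lies within the spread of the fits. Compression and an effect of the treatment cannot be told apart, because depth and treatment coincide.

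Choroid plexus genes and RNAs without poly(A) tails were both high in the untreated libraries. RNA from choroid plexus cells in the untreated cultures is a candidate explanation for the first: a second list of 22 such genes had a median log2 change of -2.28 with TTX, 21 of 22 lower, below all 10000 random lists matched on level (lowest -0.55). Ttr at 175 and Enpp2 at 111 RPKM untreated belong to the first list, which was drawn up after the data were seen. Of the first list 12 of 24 genes, and of the second 14 of 22, average at least 1 RPKM with TTX, and 0 are in another list. Retention of tailless RNA was also tested. For the choroid plexus genes, whose mRNAs carry tails, the value used was their own median of -3.61. That is the pattern itself, so this test decides nothing. For the tailless RNAs, in TTX against untreated, 61 replication-dependent histone genes had a median log2 change of 0.40. A median of -1 or lower was predicted, and the lowest member was at -0.72. This argues against retention only as far as histone RNA lacked tails here, which was not measured, and cycling cells also set its level. With Bic/4AP against untreated the histone median was -0.61, which 1135 of 10000 random lists matched on level reached or passed. That value decides neither way. The first choroid plexus list had a median log2 change as deposited of -3.61 with TTX and -3.65 with 3 h of Bic/4AP. These treatments move activity in opposite directions, and the untreated libraries are what both comparisons share. An effect of both treatments on the choroid plexus genes and tailless RNAs and a difference in preparing the untreated libraries stay open and untested.

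Bins that differed in methylation by 20 points between Bic/4AP and untreated rest on single libraries. Sampling noise of these libraries and an effect of the treatment cannot be told apart: the differences in the left and right part of a bin correlated at r = 0.00167 across bins, but with 3 CpGs needed in each part 354 of the 2369 changed bins, or 14.9%, could enter that test. Changes of regions wider than 1 kb are argued against as the source of most of the 1740 changed bins with a neighbouring bin. Of the neighbours, 50.02% differed in the direction of the changed bin, below the 55% set in advance. Such changes in a small part of these bins cannot be excluded, since the test was not tried on inserted changes wider than a bin. Wider changes also stay open for the 629 changed bins without a neighbouring bin.

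The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Bic/4AP against untreated gave 10673 genes where the highest other split gave 2, TTX against untreated 9491 where it gave 0, and Bic/4AP against TTX 11369 where it gave 1, and in each case 1 split, the real one, gave as many. Every other split mixes libraries of both treatments in each group, so the difference between treatments enters the spread inside the groups. Few calls in those splits are therefore built in, and their counts are no level for unchanged groups.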
